A study of Mus musculus with 12 samples.

How the data were processed

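RNA was measured in 12 libraries of the mouse P19 embryonal carcinoma line, 3 in each of 4 groups. Per the labels' protocols, cells were grown as embryoid bodies in 1 µM retinoic acid for 4 days, plated on laminin on day 4, exposed to 12 µM AraC from day 6 and collected on day 7. RNA was extracted with Trizol, treated with DNase and made into libraries with a stranded polyA kit. Groups were taken from the genotype labels. The values are raw counts per gene name of single libraries as deposited by the authors. They were made, per the submitters' processing notes, by alignment with STAR 2.4.2a to mouse build mm9, and the file headers name coordinate-sorted alignments. The notes also name DESeq2 without a version, while the counting program, its strand setting, the annotation and any filter are not given in the sources used here. Counts of overlapping, antisense or paralogous genes are therefore uncertain. The files give no coordinates, and genes are identified by the symbols in the files.

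The files held 34682 gene names, of which 1781 carried a suffix for repeated names and 6702 were accession-type names. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The filterByExpr function with the groups kept 15943 genes and left 18739 out for low counts. Counts were scaled with TMM factors. A quasi-likelihood model with group as its only term was fitted to all 12 libraries (8 residual degrees of freedom, common biological coefficient of variation 0.0655). Four-group pooling assumes a like spread in every group. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes of each of the 4 comparisons, and genes with an adjusted p under 0.05 were called. CPM used the TMM-scaled library totals, and correlations used log CPM with a prior count of 2. With 3 libraries against 3 there are 10 splits, so an exact permutation test of a single gene could not fall under 0.05, and the model was used instead.

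Total counts per library are given with the results. Where all libraries of a group had 0 counts, the fold is a lower bound computed against 3 counts over the group, and with 1 to 3 counts a ratio with a 95% counting interval is given. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

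Before the data were examined, the comparisons, tests, alternatives, the rule for named genes and 23 gene lists were fixed. The lists were visceral transcription factors, noradrenergic, cholinergic, dorsal inhibitory, dorsal excitatory, dorsal progenitor, ventral patterning, general neuronal, neural progenitor, pluripotency, cell cycle, glia, fibroblast and smooth muscle (mesenchyme), endoderm, muscle, neural crest, Hox paralogue groups 1 to 5, Hox paralogue groups 6 to 13 (later Hox), retinoic acid, p53 targets, interferon, stress and RNA quality. Some genes are in more than 1 list. The named genes are Phox2b and Lbx1, a fixed panel (Phox2a, Hand2, Dbh, Th, Pax2, Lhx1, Lhx5, Lmx1b, Tlx3, Gad1, Slc17a6 and Tubb3), the 5 largest rises and 5 largest falls, and for each list the 2 called members with the smallest adjusted p. The largest changes were taken among called genes with a mean of at least 5 CPM in the higher group and no overlap between libraries, without predicted, RNA and pseudogene names. Of these, those that best describe each list are printed.

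Lists were tested with camera at a preset correlation between genes of 0.01, two-sided and adjusted over the 23 lists of a comparison, and again with an estimated correlation. Where a called list is given with the preset value only, its call held with the estimated correlation, at a larger adjusted p. The overlap of both Lbx1 comparisons was set beside independent lists and 20 simulations of unchanged groups against the same Phox2b libraries. In tests on simulated data with the spread of these libraries, 200 of 15943 genes were changed 1.5-fold, 2-fold or 4-fold. The changed genes were drawn without the genes of lowest expression in the group compared against. At 1.5-fold, edgeR recovered 76.7, 90, 80 and 83.3% of the changed genes in the 4 comparisons, in the order of the report. At 2-fold it recovered 91.3, 93.8, 93.8 and 96.3%, and at 4-fold 100% in each. False calls made up 6.77, 3.57, 7.11 and 6.03% of its calls, and 11.3, 5.97, 11.2 and 10.1% of those of DESeq2. A raised list of 20 genes was found in all 4 comparisons, and 0% of 200 unchanged lists had a p under 0.05. Simulated genes were drawn independently, each with the same spread in every group. These rates may therefore not hold for genes of low expression, for lists of correlated genes, for a more variable group or where many genes change.

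The alternatives were DESeq2 in place of edgeR, size factors of the DESeq2 type and upper-quartile factors, no filter or a mean of at least 5 CPM, a fit of only the 2 groups compared, the replicate number as a block, each library left out in turn, library totals without the 20 most abundant genes, an adjusted p under 0.01 and a change of at least 2-fold. Lists were also tested on ranks. Separate Phox2b controls for both Lbx1 forms and a fit without repeated and accession-type gene names were added after seeing the data. Among the tests of explanations, a ratio taken only over genes changed with Lbx1FS and medians over fallen retinoic acid genes were replaced, since those genes had been chosen for the pattern. A count of genes called between the Lbx1 groups was dropped as a test of the knockout label, since it restated the pattern. Aligned reads were not analysed here, so transgene and endogenous transcripts were not separated.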

Results

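RNA was sequenced from 12 libraries of P19 cells, a mouse embryonal carcinoma line that forms neurons when exposed to retinoic acid. The cells were kept as embryoid bodies in 1 µM retinoic acid for 4 days and plated on laminin on day 4. Cytosine arabinoside (AraC), which kills dividing cells, was added at 12 µM on day 6, and RNA was collected on day 7. The 4 groups of 3 libraries each were untransduced cells, cells transduced with Phox2b (the Phox2b group), and cells transduced with Phox2b together with a Flag-tagged Lbx1. In the last pair of groups the Lbx1 was either wild type (the Lbx1WT group) or a frameshift form (the Lbx1FS group). The labels place both Lbx1 groups on an Lbx1 knockout background and do not mention a knockout for the Phox2b group. Each comparison of an Lbx1 group with the Phox2b group therefore also spans this difference in the labels.

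Total counts were 27586088, 18011810 and 23010272 in untransduced replicates 1 to 3, and 31452800, 26365777 and 25843859 in the Phox2b group. They were 25804554, 23641229 and 28166995 in the Lbx1WT group, and 30796766, 22443278 and 25821401 in the Lbx1FS group. Of 34682 gene names, 15943 passed the filter on low counts and were tested. Expression is given as CPM, counts scaled to library totals, with TMM factors, as mean ± SD over n = 3 libraries. The file headers name a single clone for the 3 libraries of each transduced group, and the labels do not say whether libraries came from separate cultures. The adjusted p-values therefore measure only the spread between these libraries. Within groups, the correlation of log CPM between libraries, taken across genes, was 0.988 to 0.995. It was 0.908 to 0.934 between the untransduced and the transduced groups, 0.985 to 0.989 between the Phox2b and Lbx1WT groups, 0.960 to 0.968 between the Phox2b and Lbx1FS groups, and 0.971 to 0.975 between the Lbx1 groups.

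A nuclear RNA and the mitochondrial transcripts set the Lbx1FS libraries apart. Malat1, a nuclear long noncoding RNA, stood at 576 ± 147 CPM in the Lbx1FS group, against 1177 ± 71.5 in untransduced cells, 1061 ± 134 in the Phox2b group and 1096 ± 56.6 in the Lbx1WT group. Mitochondrially encoded genes took 1.19 ± 0.242% of the counts in the Lbx1FS group and 1.66 to 1.73% on average in the other groups. Replicate 3 of the Lbx1FS group was lowest in both, at 406 CPM of Malat1 and 0.935% mitochondrial counts. These differences accompany every gene group compared with the Lbx1FS libraries.

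Phox2b, the homeodomain factor of visceral neurons that was transduced, was low in untransduced cells and present in all 9 transduced libraries at unequal levels. It stood at 1.79, 1.34 and 1.65 CPM in untransduced replicates 1 to 3, and at 105, 98.5 and 122.9 CPM in the Phox2b group. It stood at 20.4, 21.4 and 28.4 CPM in the Lbx1WT group, and at 13.2, 9.60 and 17.4 CPM in the Lbx1FS group. Lbx1, the homeodomain factor of dorsal interneurons, had 57.8, 57.8 and 53.4 CPM in untransduced cells and 69.2, 63.1 and 107 CPM in the Phox2b group. It had 48.5, 55.4 and 64.2 CPM in the Lbx1WT group and 77.9, 55.9 and 105 CPM in the Lbx1FS group. Gene counts do not separate transduced from endogenous transcripts, nor a knocked-out transcript that is still made, so the Lbx1 counts neither check the knockout label nor the transgene.

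**Figure D1:**
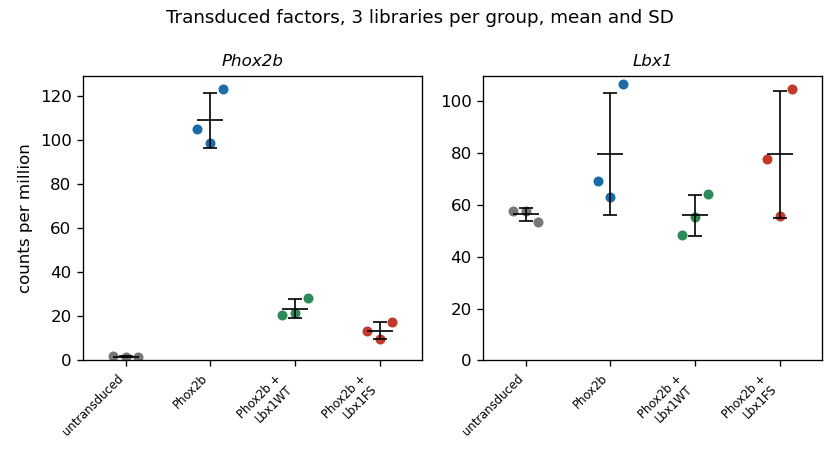
Expression of Phox2b and Lbx1 in CPM (vertical axes, from 0) in each of the 4 groups (horizontal axes). Points are the 3 libraries, and the bar with its whiskers is the mean ± SD; Phox2b averaged 109 CPM in the Phox2b group, 23.4 in the Lbx1WT group and 13.4 in the Lbx1FS group.

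The comparison of the Phox2b group with untransduced cells asks which transcripts differ in P19 cells that carry Phox2b. Phox2b itself rose from 1.59 ± 0.229 to 109 ± 12.6 CPM (n = 3 each; log2 fold change 6.06, SE 0.22, edgeR adjusted p = 3.58e-13). Genes of dorsal inhibitory neurons were lower with Phox2b, among them the paired-box factor Pax2, at 46.4 ± 1.98 against 199 ± 6.60 CPM (log2 fold change -2.10, SE 0.11). The glycine transporter gene Slc6a5 fell from 76.8 ± 2.38 to 4.68 ± 0.391 CPM. Cell cycle genes were higher, with the ribonucleotide reductase subunit gene Rrm2 at 302 ± 4.61 against 32.4 ± 0.743 CPM and the topoisomerase gene Top2a at 277 ± 4.17 against 39.0 ± 0.403 CPM. The p53 target Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 32.7 ± 1.72 to 300 ± 8.66 CPM.

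Neuronal lists moved in different directions between these groups. None of the 16 measured dorsal inhibitory genes rose, 14 fell and 2 were not called (median log2 fold change -2.28; camera adjusted p = 1.54e-15). With an estimated correlation, camera gave this list an adjusted p of 0.00102. Pax8 fell from 113 ± 2.35 to 10.2 ± 0.855 CPM, and Gad1, which encodes a GABA-synthesising enzyme, fell from 198 ± 6.25 to 70.2 ± 1.17 CPM. The LIM homeodomain genes Lhx1 (135 ± 8.54 against 329 ± 6.88 CPM) and Lhx5 (7.17 ± 1.44 against 61.5 ± 0.426 CPM) fell as well. Of 25 general neuronal genes, 18 fell and 6 rose (median -0.62; adjusted p = 0.00240), with the synaptotagmin gene Syt4 at 96.1 ± 0.987 against 353 ± 7.99 CPM. The neuronal tubulin gene Tubb3 was not called, at 1228 ± 23.6 against 1361 ± 46.6 CPM (log2 fold change -0.15, adjusted p = 0.133), and was called without Lbx1FS replicate 2 at the same fold change and when only these 2 groups were fitted (-0.07). Of 17 dorsal excitatory genes, 9 fell and 5 rose (adjusted p = 0.0288). That call was lost with the adjusted p = 0.0674 with an estimated correlation, in a range of 0.0139 to 0.151 over the alternatives. In this list the glutamate transporter gene Slc17a6 fell from 85.0 ± 0.499 to 22.5 ± 1.00 CPM, the homeodomain gene Lmx1b from 16.3 ± 0.783 to 0.567 ± 0.149 CPM, Tlx3 from 18.002 ± 1.94 to 3.39 ± 0.964 CPM and Pou4f1 from 121 ± 1.63 to 24.0 ± 1.76 CPM. Of 8 cholinergic genes, 6 rose and 1 fell (median 1.23; adjusted p = 0.0201, and adjusted p = 0.0674 with an estimated correlation). Prph, the gene of the intermediate filament peripherin, rose from 2.81 ± 0.560 to 18.3 ± 1.51 CPM.

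Visceral transcription factor genes rose in 10 of 15 cases and fell in 3 without a call for the list (adjusted p = 0.0754), although the list was called without Phox2b replicate 2 (adjusted p = 0.0390, range 0.0249 to 0.313 over the alternatives). The T-box gene Tbx2 rose from 2.39 ± 0.354 to 38.4 ± 4.96 CPM and Gata3 from 0.261 ± 0.0513 to 4.94 ± 0.376 CPM. Phox2a, the paralogue of Phox2b, was not called at 1.78 ± 0.675 against 1.11 ± 0.473 CPM (log2 fold change 0.66, SE 0.32, adjusted p = 0.0785). It was called without untransduced replicate 3 (log2 fold change 1.05) or without Phox2b replicate 1 (0.87), with the replicate number as a block (0.66), and when only these 2 groups were fitted (0.73). Th, the gene of the rate-limiting enzyme of catecholamine synthesis, rose from 0.543 ± 0.139 to 1.43 ± 0.178 CPM. Hand2 and Dbh had too few counts in any group to be tested. Of 15 noradrenergic and autonomic genes, 7 rose and 7 fell, with a median of 0.0093 and a mean of -0.52, and the list was called downward (adjusted p = 0.0201, and adjusted p = 0.0674 with an estimated correlation). The neuropeptide gene Npy fell from 41.2 ± 2.91 to 0.482 ± 0.170 CPM.

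Lists of dividing and non-neuronal cells were mostly higher with Phox2b. All 24 cell cycle genes rose (median 2.43; camera adjusted p = 1.06e-40), as did all 15 p53 targets (median 2.44; adjusted p = 1.18e-30), with Btg2 at 170 ± 2.28 against 11.9 ± 0.590 CPM. With an estimated correlation, camera gave an adjusted p of 3.69e-04 for cell cycle genes and 3.53e-05 for p53 targets. Of 18 fibroblast and smooth muscle genes, 16 rose and 1 fell (median 3.03; adjusted p = 8.74e-17), with the collagen gene Col3a1 at 175 ± 4.92 against 10.6 ± 0.153 CPM. Of 16 endoderm genes, 13 rose and 1 fell (median 2.66; adjusted p = 5.31e-08), with Sparc, which encodes a matrix protein, at 464 ± 10.3 against 71.8 ± 2.29 CPM. Of 10 neural crest genes, 9 rose (adjusted p = 3.15e-04, and adjusted p = 0.0611 with an estimated correlation). Of 11 glial genes, 6 rose and 3 fell (adjusted p = 0.00594, and adjusted p = 0.0674 with an estimated correlation). Of 17 neural progenitor genes, 11 rose and 6 fell (adjusted p = 3.83e-04, and adjusted p = 0.178 with an estimated correlation), with the intermediate filament gene Vim at 675 ± 36.5 against 142 ± 3.04 CPM. Of 16 dorsal progenitor genes, 10 rose and 4 fell (adjusted p = 0.0359, and adjusted p = 0.313 with an estimated correlation). Without Lbx1FS replicate 2 the dorsal progenitor list was not called (adjusted p = 0.0540, range 0.0154 to 0.313 over the alternatives).

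Of 17 retinoic acid genes, 13 rose and 1 fell (median 0.88; adjusted p = 0.00892, and adjusted p = 0.116 with an estimated correlation). The retinol transporter gene Stra6 rose from 13.4 ± 1.05 to 51.2 ± 2.64 CPM, and the retinol-binding protein gene Rbp1 fell from 27.2 ± 0.214 to 0.0966 ± 0.0803 CPM. Among 14 Hox genes of paralogue groups 1 to 5, 8 rose and 1 fell without a call for the list (adjusted p = 0.0606). That list was called without Phox2b replicate 2 (adjusted p = 0.0450, range 0.0121 to 0.344 over the alternatives). The lists of ventral patterning, pluripotency, muscle, later Hox, interferon, stress and RNA quality genes were not called either, with adjusted p from 0.217 to 0.927. In the stress list the median was -0.08 and the mean 0.13. Adjusted over the list alone, the counts were the same for every list except glia, where 7 genes rose.

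The largest rises by the fixed rule, after Phox2b, were in the Wnt ligand gene Wnt6 (19.8 ± 3.99 against 0.184 ± 0.108 CPM), Cxcl15 (10.2 ± 1.19 against 0.0990 ± 0.0677 CPM), the Wnt antagonist gene Notum (16.4 ± 1.08 against 0.151 ± 0.0331 CPM) and Osr2 (5.03 ± 0.642 against 0.0965 ± 0.0889 CPM). The largest falls included genes with no count in the Phox2b libraries. Against a floor of 3 counts over the group, Nap1l3 was at least 859-fold lower, the guanylate cyclase subunit gene Gucy1b3 at least 246-fold lower and the Y-linked gene Usp9y, which has an X-linked paralogue, at least 215-fold lower. Meg3, an imprinted noncoding RNA, fell from 916 ± 11.5 to 0.522 ± 0.282 CPM (log2 fold change -10.77, SE 0.12, adjusted p = 8.64e-19). Tram1l1 had 3 counts in the Phox2b group against 3317 in untransduced cells, a ratio of 1471 with a 95% counting interval of 503 to 7138.

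In all, edgeR's quasi-likelihood test called 10691 of the 15943 genes at an adjusted p under 0.05 (67.1%), of which 4831 rose and 5860 fell. The balance of rises and falls depended on the scaling and fit, at 5212 and 5099 with DESeq2, 5249 and 5171 with DESeq2-type size factors, 5023 and 5592 with upper-quartile factors, and 5783 and 5511 when only these 2 groups were fitted. A change of at least 2-fold was found for 2492 genes that rose and 1217 that fell. The call for Lbx1 (56.3 ± 2.54 against 79.7 ± 23.7 CPM, log2 fold change 0.50, SE 0.20, adjusted p = 0.0343) was lost with DESeq2, without untransduced replicate 1 (0.52), 2 (0.52) or 3 (0.46), and without Phox2b replicate 3 (0.23). Transduction and clone differ together with the group here.

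**Figure D2:**
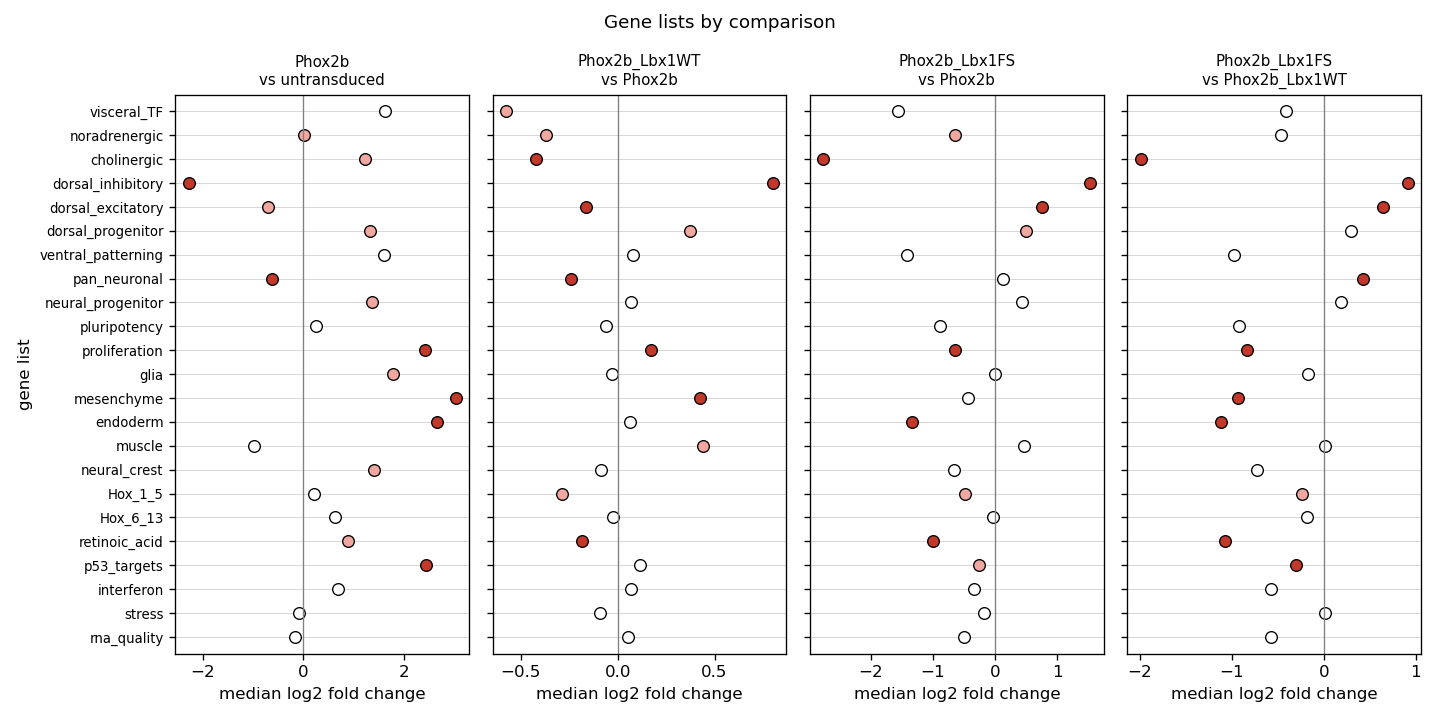
Median log2 fold change (horizontal axes, a separate scale for each comparison) of the 23 fixed gene lists (vertical axis) in the 4 comparisons. Dark red points are lists called by camera with the preset and with an estimated correlation, pale points lists called with the preset correlation only, and white points lists not called; the dorsal inhibitory list was called in all 4 comparisons, downward with Phox2b alone (median -2.28) and upward in the others.

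The comparison of the Lbx1WT group with the Phox2b group asks what differs between cells labelled as transduced with Phox2b and wild-type Lbx1 and cells with Phox2b alone; Lbx1 counts were not higher in the Lbx1WT group. Genes of dorsal inhibitory neurons were higher with Lbx1WT. Pax8 rose from 10.2 ± 0.855 to 70.6 ± 3.05 CPM (n = 3 each; log2 fold change 2.79, SE 0.07, edgeR adjusted p = 4.54e-13), Gad1 from 70.2 ± 1.17 to 168 ± 6.58 CPM (1.26, SE 0.05) and Pax2 from 46.4 ± 1.98 to 90.1 ± 6.90 CPM (0.96, SE 0.11). The glutamate transporter gene Slc17a6 fell from 22.5 ± 1.00 to 6.29 ± 0.860 CPM (log2 fold change -1.83, SE 0.08), and the motor neuron factor gene Lhx3 from 11.3 ± 1.35 to 1.23 ± 0.118 CPM. Phox2b was itself lower, at 23.4 ± 4.35 against 109 ± 12.6 CPM (log2 fold change -2.22, SE 0.15, adjusted p = 3.87e-08).

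Of 16 dorsal inhibitory genes, 9 rose, 1 fell and 6 were not called (median 0.80; camera adjusted p = 4.24e-22). With an estimated correlation, camera gave this list an adjusted p of 7.72e-04. Lhx1 (120 ± 3.14 against 135 ± 8.54 CPM) and Lhx5 (7.90 ± 0.489 against 7.17 ± 1.44 CPM) were not called, although Lhx1 was called without Lbx1FS replicate 2 (log2 fold change -0.16) or 3 (-0.16) and when only these 2 groups were fitted (-0.18). None of 8 cholinergic genes rose and 5 fell (median -0.42; adjusted p = 5.30e-09), with Prph at 6.91 ± 0.268 against 18.3 ± 1.51 CPM. Of 15 visceral transcription factor genes, 7 fell and 1 rose (adjusted p = 0.00296, and adjusted p = 0.0939 with an estimated correlation). Adjusted over the list alone, 9 of them fell. Tbx2 fell from 38.4 ± 4.96 to 24.9 ± 1.68 CPM and the zinc finger gene Insm1 from 15.5 ± 1.42 to 10.4 ± 0.0539 CPM. Phox2a stood at 0.875 ± 0.0876 against 1.78 ± 0.675 CPM (log2 fold change -1.005, SE 0.32, adjusted p = 0.0400). Its call was lost without Lbx1WT replicate 1 (-1.09), 2 (-0.96) or 3 (-0.96) and without Phox2b replicate 2 (-1.07) or 3 (-0.66). Of 15 noradrenergic genes, 6 fell and 2 rose (adjusted p = 0.0419, and adjusted p = 0.0939 with an estimated correlation). That call was also lost without Lbx1WT replicate 3 (adjusted p = 0.0915), Phox2b replicate 2 (0.0505) or Phox2b replicate 3 (0.0514), in a range of 0.0175 to 0.0939 over the alternatives. Npy rose from 0.482 ± 0.170 to 3.67 ± 0.381 CPM, and Th was not called at 1.01 ± 0.0571 against 1.43 ± 0.178 CPM.

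Of 17 dorsal excitatory genes, 3 rose and 3 fell (median -0.16; adjusted p = 0.00635), and the call was lost on ranks (adjusted p = 0.226, range 0.00243 to 0.226 over the alternatives). Adcyap1, a neuropeptide gene, fell from 34.2 ± 1.59 to 15.8 ± 0.761 CPM. Lmx1b stood at 1.25 ± 0.379 against 0.567 ± 0.149 CPM (log2 fold change 1.13, adjusted p = 0.0145), a call lost without Lbx1WT replicate 3 (0.89) or Phox2b replicate 3 (0.96). Tlx3 was not called at 3.57 ± 1.25 against 3.39 ± 0.964 CPM. Of 16 dorsal progenitor genes, 7 rose and 4 fell (adjusted p = 0.00286, and adjusted p = 0.173 with an estimated correlation), or 7 and 5 when adjusted over the list alone. The zinc finger genes Zic1 (311 ± 13.1 against 140 ± 8.99 CPM) and Zic3 (38.5 ± 1.32 against 18.6 ± 0.609 CPM) rose. Of 25 general neuronal genes, 15 fell and 2 rose (median -0.24; adjusted p = 2.85e-08), with the neurofilament gene Nefl at 90.9 ± 2.34 against 236 ± 23.4 CPM. Tubb3 stood at 977 ± 80.2 against 1228 ± 23.6 CPM (log2 fold change -0.33, adjusted p = 0.0147). The Tubb3 call was lost without Lbx1WT replicate 1 (-0.27) or 2 (-0.32) and without Phox2b replicate 2 (-0.31) or 3 (-0.32).

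Cell cycle genes rose in 14 of 24 cases and none fell (median 0.17; adjusted p = 3.82e-05), or 15 when adjusted over the list alone, with Top2a at 368 ± 14.97 against 277 ± 4.17 CPM. Of 18 fibroblast and smooth muscle genes, 10 rose and 2 fell (median 0.42; adjusted p = 1.95e-04), or 11 and 2 when adjusted over the list alone. Col3a1 rose from 175 ± 4.92 to 313 ± 0.586 CPM and Tagln, which encodes a smooth muscle protein, fell from 19.2 ± 1.35 to 8.65 ± 0.682 CPM. Of 17 retinoic acid genes, 6 fell and 2 rose (median -0.19; adjusted p = 1.15e-06), or 7 and 2 when adjusted over the list alone. The retinoic acid hydroxylase genes Cyp26b1 (783 ± 20.3 against 1808 ± 9.32 CPM) and Cyp26a1 (4.40 ± 0.459 against 19.1 ± 0.775 CPM) fell. None of 14 Hox genes of paralogue groups 1 to 5 rose and 10 fell (median -0.29; adjusted p = 2.63e-05, and adjusted p = 0.0939 with an estimated correlation), with Hoxa1 at 94.1 ± 3.24 against 129 ± 4.89 CPM. Of 9 muscle genes, 3 rose (adjusted p = 0.0428, and adjusted p = 0.0939 with an estimated correlation). The muscle call was also lost without Lbx1WT replicate 3 (adjusted p = 0.0915), Lbx1FS replicate 2 (0.0905) or 3 (0.0729), or Phox2b replicate 2 (0.0601), in a range of 0.0200 to 0.143 over the alternatives.

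The ventral patterning list was not called (adjusted p = 0.0515; median 0.08, mean -0.45), with Evx1, a homeobox gene of ventral interneurons, at 0.541 ± 0.190 against 7.05 ± 0.382 CPM. It was called without untransduced replicate 1 (adjusted p = 0.0481) or 3 (0.0435), Lbx1FS replicate 1 (0.0457), or Phox2b replicate 1 (0.0343) or 2 (0.0176), in a range of 0.0176 to 0.945 over the alternatives. The lists of neural progenitor, pluripotency, glia, endoderm, neural crest, later Hox, p53 target, interferon, stress and RNA quality genes were not called, with adjusted p from 0.112 to 0.985. Among these, median, mean and test direction differed in sign for neural progenitor, glia, endoderm, later Hox and RNA quality genes. Adjusted over the list alone, p53 targets had 5 rises in place of 4, neural crest genes 2 in place of 1, later Hox genes 3 falls in place of 2 and stress genes 1 fall in place of 2. The other lists kept their counts.

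By the fixed rule, the largest rises were in Got1l1 (12.5 ± 0.446 against 0.0903 ± 0.0468 CPM), Ddit4l (18.6 ± 0.532 against 0.168 ± 0.0873 CPM), Ric3, which encodes a chaperone of nicotinic receptors (24.1 ± 0.549 against 0.400 ± 0.159 CPM), the imprinted adaptor gene Grb10 (133 ± 1.81 against 7.42 ± 0.307 CPM) and Cul9 (46.9 ± 2.43 against 3.05 ± 0.359 CPM). Besides Evx1, Lhx3 and Phox2b, the largest falls were in Pcdhga2 (0.559 ± 0.0961 against 5.59 ± 0.524 CPM) and Nckap1l (5.43 ± 0.211 against 25.6 ± 1.31 CPM). Pcdhga2 shares exons with other genes of its cluster, so its counts are uncertain. Lbx1 was not called, at 56.0 ± 7.84 against 79.7 ± 23.7 CPM (log2 fold change -0.51, SE 0.19, adjusted p = 0.0893). It was called without Lbx1FS replicate 2 (-0.50) or 3 (-0.50), with the replicate number as a block (-0.48), with no filter on low counts (-0.51, adjusted p = 0.00534), and when only these 2 groups were fitted (-0.52, adjusted p = 0.00448).

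In all, edgeR called 2694 genes (16.9%), of which 1404 rose and 1290 fell, and 147 rose and 194 fell by at least 2-fold. The count depended on single libraries: it was 1540 without Lbx1WT replicate 1, 1655 without Lbx1WT replicate 2, 1579 without Phox2b replicate 3 and 4292 without Lbx1FS replicate 2. When the spread was estimated from these 2 groups alone it was 4588.

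The comparison of the Lbx1FS group with the Phox2b group asks the same for the frameshift form. Most retinoic acid genes were lower with Lbx1FS, most dorsal inhibitory genes were higher, and dorsal excitatory genes moved both ways. Cyp26b1 fell from 1808 ± 9.32 to 18.3 ± 0.914 CPM (n = 3 each; log2 fold change -6.62, SE 0.05, edgeR adjusted p = 5.94e-21), Cyp26a1 from 19.1 ± 0.775 to 0.284 ± 0.0439 CPM, and Dhrs3, which encodes a retinaldehyde reductase, from 120 ± 1.31 to 3.30 ± 0.650 CPM. Pax8 rose from 10.2 ± 0.855 to 127 ± 9.91 CPM (log2 fold change 3.63, SE 0.07) and Slc17a6 from 22.5 ± 1.00 to 99.0 ± 5.13 CPM (2.14, SE 0.07). Phox2b was at 13.4 ± 3.93 against 109 ± 12.6 CPM (log2 fold change -3.01, SE 0.16, adjusted p = 1.87e-10), and Lbx1 did not differ detectably (79.6 ± 24.5 against 79.7 ± 23.7 CPM, adjusted p = 0.996).

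Of 17 retinoic acid genes, 11 fell and 1 rose (median -0.99; camera adjusted p = 1.78e-27), or 12 and 1 when adjusted over the list alone. With an estimated correlation, camera gave this list an adjusted p of 4.86e-05. Of 16 dorsal inhibitory genes, 11 rose and 3 fell (median 1.53; adjusted p = 9.68e-15). Slc6a5 rose from 4.68 ± 0.391 to 51.9 ± 1.13 CPM, Gad1 from 70.2 ± 1.17 to 270 ± 17.1 CPM, Pax2 from 46.4 ± 1.98 to 194 ± 41.1 CPM and Lhx5 from 7.17 ± 1.44 to 13.5 ± 2.73 CPM. Lhx1 was not called at 145 ± 26.5 against 135 ± 8.54 CPM (log2 fold change 0.11), was called without Lbx1FS replicate 2 (0.22), and had a value of -0.05 without Lbx1FS replicate 3. Of 17 dorsal excitatory genes, 8 rose and 5 fell (median 0.75; adjusted p = 5.26e-07), or 9 and 5 when adjusted over the list alone. This call was lost on ranks (adjusted p = 0.135, range 8.32e-08 to 0.135 over the alternatives). Ebf2, a transcription factor gene, rose from 4.61 ± 0.391 to 71.5 ± 3.54 CPM and Lmx1b from 0.567 ± 0.149 to 7.79 ± 1.42 CPM. Tlx3 was not called at 5.58 ± 3.01 against 3.39 ± 0.964 CPM (log2 fold change 0.75, adjusted p = 0.0568). It was called without Lbx1WT replicate 3 (0.74), Lbx1FS replicate 2 (1.06) or Phox2b replicate 3 (0.99), with the replicate number as a block (0.71), and with no filter on low counts (0.75, adjusted p = 0.00639).

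All 8 cholinergic genes fell (median -2.76; adjusted p = 5.24e-09), with Prph at 1.08 ± 0.332 against 18.3 ± 1.51 CPM and Lhx3 at 0.190 ± 0.0389 against 11.3 ± 1.35 CPM. Visceral transcription factor genes fell in 10 of 15 cases and rose in 4 without a call for the list (adjusted p = 0.159), with Tbx2 at 2.99 ± 0.460 against 38.4 ± 4.96 CPM. Phox2a fell to 0.821 ± 0.156 CPM (log2 fold change -1.11, adjusted p = 0.00771), a call lost without Phox2b replicate 3 (-0.78). Of 15 noradrenergic genes, 7 fell and 4 rose (adjusted p = 0.0381, and adjusted p = 0.0862 with an estimated correlation), or 8 and 4 when adjusted over the list alone. That call was also lost without Lbx1FS replicate 2 (adjusted p = 0.0668) or 3 (0.0564), in a range of 0.0205 to 0.182 over the alternatives. Npy rose from 0.482 ± 0.170 to 21.1 ± 0.467 CPM and Th from 1.43 ± 0.178 to 2.46 ± 0.574 CPM. By at least 2-fold, 4 noradrenergic genes fell and 1 rose. Of 16 dorsal progenitor genes, 7 rose and 6 fell (adjusted p = 0.0381, and adjusted p = 0.408 with an estimated correlation). The dorsal progenitor call was also lost without Lbx1FS replicate 3 (adjusted p = 0.0699), Phox2b replicate 1 (0.0689) or 2 (0.0604), and with the replicate number as a block (adjusted p = 0.232), in a range of 0.00271 to 0.527 over the alternatives.

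Of 24 cell cycle genes, 23 fell and 1 rose (median -0.64; adjusted p = 5.17e-09), with Ube2c, which encodes a ubiquitin-conjugating enzyme of mitosis, at 27.2 ± 1.54 against 58.5 ± 3.40 CPM. Of 16 endoderm genes, none rose and 14 fell (median -1.33; adjusted p = 8.27e-06), with the keratin gene Krt8 at 8.43 ± 0.853 against 27.1 ± 1.62 CPM. None of 14 Hox genes of paralogue groups 1 to 5 rose and 11 fell (median -0.49; adjusted p = 8.79e-06, and adjusted p = 0.0833 with an estimated correlation), with Hoxa1 at 41.6 ± 0.582 against 129 ± 4.89 CPM. None of 15 p53 targets rose and 12 fell (median -0.27; adjusted p = 0.0184, and adjusted p = 0.0642 with an estimated correlation). The other lists (ventral patterning, general neuronal, neural progenitor, pluripotency, glia, mesenchyme, muscle, neural crest, later Hox, interferon, stress and RNA quality) were not called, with adjusted p from 0.0679 to 0.778. Of 26 RNA quality members only 6 were measured, of which 2 rose and 3 fell, so this list does not show equal RNA quality. The neural crest list was called without Phox2b replicate 2 (adjusted p = 0.0384, range 0.0251 to 0.303 over the alternatives). Of 25 general neuronal genes, 12 rose and 10 fell, and 2 rose and 3 fell by at least 2-fold. Among the rises were Nhlh1, a basic helix-loop-helix factor gene of young neurons, at 65.3 ± 3.06 against 6.98 ± 0.135 CPM, and the adhesion gene Cntn2 at 571 ± 41.2 against 148 ± 4.23 CPM. Tubb3 was not called at 1341 ± 212 against 1228 ± 23.6 CPM (log2 fold change 0.13) and was called without Lbx1FS replicate 2 (0.25). Counts adjusted over the list alone were those over all genes for every list not given above with its own count.

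By the fixed rule, Ric3 (34.7 ± 1.59 against 0.400 ± 0.159 CPM), Ddit4l (10.9 ± 0.846 against 0.168 ± 0.0873 CPM), Npy and Gbx2 (15.9 ± 2.10 against 0.747 ± 0.176 CPM) were among the largest rises. Magee2 had 536 counts against 2 in the Phox2b group, a ratio of 300 with a 95% counting interval of 82.6 to 2481. Besides Cyp26b1, Cyp26a1 and Lhx3, the largest falls were in the calcium-binding protein gene Calb1 (0.137 ± 0.174 against 10.6 ± 0.359 CPM) and in Slc26a5 (0.116 ± 0.0355 against 5.74 ± 0.736 CPM). In all, edgeR called 9330 genes (58.5%), of which 4658 rose and 4672 fell (4260 and 4917 with DESeq2, 4294 and 4996 with DESeq2-type size factors, 4227 and 5051 with upper-quartile factors), and 480 rose and 1599 fell by at least 2-fold. When only these 2 groups were fitted, 8443 genes were called.

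**Figure D3:**
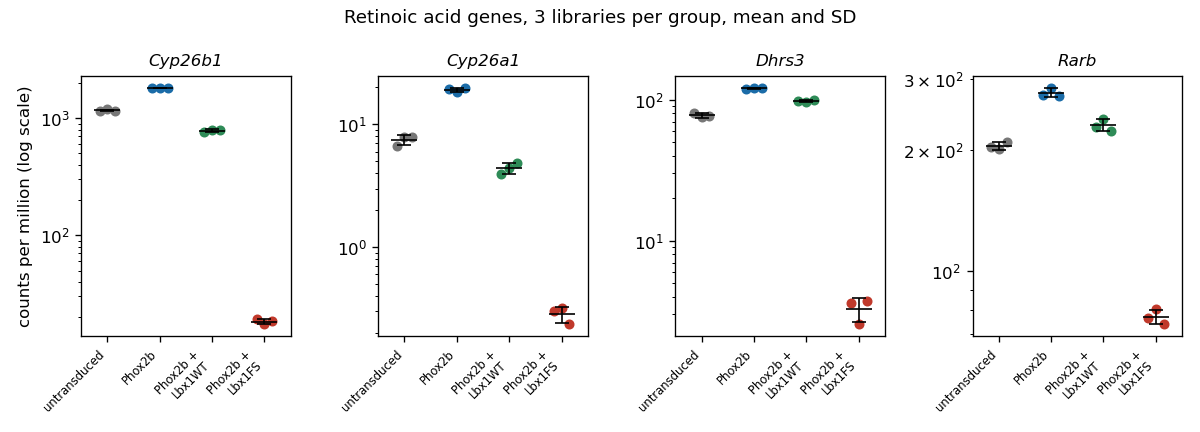
Expression of the retinoic acid genes Cyp26b1, Cyp26a1, Dhrs3 and Rarb in CPM (vertical axes, log scale) in each of the 4 groups (horizontal axes). Points are the 3 libraries and the bar with its whiskers is the mean ± SD; Cyp26b1 averaged 1808 CPM in the Phox2b group, 783 in the Lbx1WT group and 18.3 in the Lbx1FS group, and the receptor gene Rarb, chosen after its values were seen, averaged 277, 230 and 77.1 CPM.

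Wild-type and frameshift Lbx1 are compared directly between the Lbx1FS and Lbx1WT groups, which share the labelled knockout background. Slc17a6 was higher with Lbx1FS, at 99.0 ± 5.13 against 6.29 ± 0.860 CPM (n = 3 each; log2 fold change 3.97, SE 0.08, edgeR adjusted p = 5.24e-15), as was Prrxl1, a homeodomain factor gene of dorsal sensory circuits, at 8.72 ± 0.302 against 0.668 ± 0.207 CPM (3.68, SE 0.18). Inhibitory genes were higher too, with Slc6a5 at 51.9 ± 1.13 against 20.1 ± 2.04 CPM, Pax2 at 194 ± 41.1 against 90.1 ± 6.90 CPM and Gad1 at 270 ± 17.1 against 168 ± 6.58 CPM. Cyp26b1 was lower, at 18.3 ± 0.914 against 783 ± 20.3 CPM (log2 fold change -5.42, SE 0.05, adjusted p = 6.85e-20), and Dhrs3 at 3.30 ± 0.650 against 98.1 ± 1.07 CPM (-4.88, SE 0.08). Phox2b was at 13.4 ± 3.93 against 23.4 ± 4.35 CPM (log2 fold change -0.80, SE 0.16, adjusted p = 6.65e-04).

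Of 17 dorsal excitatory genes, 8 rose and 2 fell (median 0.65; camera adjusted p = 1.50e-12), with Ebf2 at 71.5 ± 3.54 against 9.58 ± 0.429 CPM and Lmx1b at 7.79 ± 1.42 against 1.25 ± 0.379 CPM. Tlx3 was not called at 5.58 ± 3.01 against 3.57 ± 1.25 CPM (log2 fold change 0.65, adjusted p = 0.101). It was called without Lbx1WT replicate 3 (0.97) or Lbx1FS replicate 2 (0.96) and with no filter on low counts (0.66). Of 16 dorsal inhibitory genes, 12 rose and 3 fell (median 0.91; adjusted p = 1.17e-05). One that fell was Slc6a1, the gene of a GABA transporter, at 8.71 ± 1.24 against 33.5 ± 1.45 CPM. Lhx5 rose from 7.90 ± 0.489 to 13.5 ± 2.73 CPM. Lhx1 stood at 145 ± 26.5 against 120 ± 3.14 CPM (log2 fold change 0.27, adjusted p = 0.0193), a call lost without Lbx1WT replicate 1 (0.24) or 2 (0.25) or Lbx1FS replicate 3 (0.11), and when only these 2 groups were fitted (0.27). Of 25 general neuronal genes, 15 rose and 6 fell (median 0.42; adjusted p = 2.67e-04), with Nhlh1 at 65.3 ± 3.06 against 11.01 ± 0.785 CPM and Tubb3 at 1341 ± 212 against 977 ± 80.2 CPM. All 8 cholinergic genes fell (median -1.99; adjusted p = 1.05e-04), with Prph at 1.08 ± 0.332 against 6.91 ± 0.268 CPM. Npy (21.1 ± 0.467 against 3.67 ± 0.381 CPM) and Th (2.46 ± 0.574 against 1.01 ± 0.0571 CPM) rose, while of all 15 noradrenergic genes 5 rose and 8 fell (median -0.47). Phox2a was not called (0.821 ± 0.156 against 0.875 ± 0.0876 CPM).

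**Figure D4:**
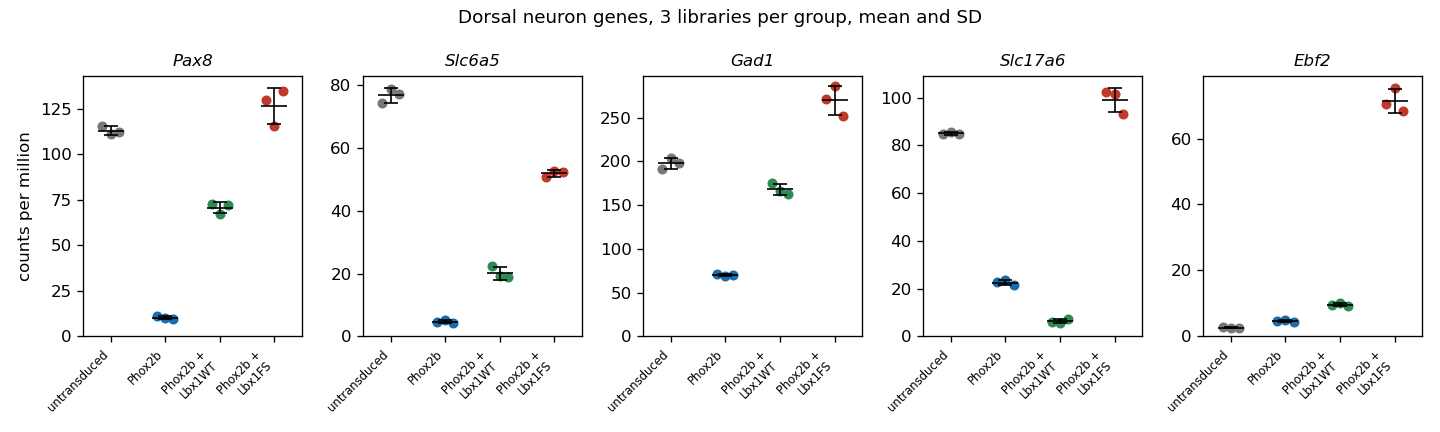
Expression of the dorsal neuron genes Pax8, Slc6a5, Gad1, Slc17a6 and Ebf2 in CPM (vertical axes, from 0) in each of the 4 groups (horizontal axes). Points are the 3 libraries and the bar with its whiskers is the mean ± SD; Slc17a6 averaged 22.5 CPM in the Phox2b group, 6.29 in the Lbx1WT group and 99.0 in the Lbx1FS group, while Gad1 averaged 70.2, 168 and 270 CPM.

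Retinoic acid genes fell in 12 of 17 cases and rose in 2 (median -1.07; adjusted p = 4.28e-26). With an estimated correlation, camera gave this list an adjusted p of 5.93e-05. Of 24 cell cycle genes, none rose and 23 fell (median -0.84; adjusted p = 5.36e-19), with Top2a at 208 ± 12.0 against 368 ± 14.97 CPM. Of 16 endoderm genes, none rose and 14 fell (median -1.12; adjusted p = 1.19e-06), with Dab2, which encodes an endocytic adaptor, at 13.7 ± 1.25 against 46.5 ± 4.27 CPM. Of 18 fibroblast and smooth muscle genes, 14 fell and 2 rose (median -0.93; adjusted p = 0.00906), or 15 and 2 when adjusted over the list alone. The 2 that rose were the smooth muscle genes Acta2 (153 ± 10.4 against 45.7 ± 0.336 CPM) and Tagln (49.3 ± 3.25 against 8.65 ± 0.682 CPM). The mesenchyme call was lost among genes with a mean of at least 5 CPM (adjusted p = 0.110, range 1.43e-04 to 0.110 over the alternatives). None of 15 p53 targets rose and 12 fell (median -0.31; adjusted p = 2.08e-04), or 13 when adjusted over the list alone. Of 14 Hox genes of paralogue groups 1 to 5, 8 fell and 1 rose (adjusted p = 0.00444, and adjusted p = 0.257 with an estimated correlation). The lists of visceral transcription factor, noradrenergic, dorsal progenitor, ventral patterning, neural progenitor, pluripotency, glia, muscle, neural crest, later Hox, interferon, stress and RNA quality genes were not called, with adjusted p from 0.10 to 0.921. Neural progenitor genes were called without Lbx1FS replicate 2 (adjusted p = 0.0210, range 0.0210 to 0.569 over the alternatives). Muscle and stress genes had medians just above 0 (0.00995 and 0.00876) and means below it (-0.20 and -0.21). Adjusted over the list alone, ventral patterning genes had 3 rises in place of 2, pluripotency genes 4 falls in place of 3, glial genes 2 rises and 7 falls in place of 1 and 6, and neural crest genes 3 rises in place of 2. The other lists kept their counts.

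By the fixed rule the largest rises also included the smooth muscle actin gene Actg2 (14.99 ± 1.62 against 0.429 ± 0.157 CPM), Pcdhga2 (7.84 ± 0.697 against 0.559 ± 0.0961 CPM) and Spp1, the gene of the matrix protein osteopontin (19.8 ± 2.62 against 2.08 ± 0.185 CPM). Actins are close paralogues and Pcdhga2 shares exons within its cluster, so both counts are uncertain. The largest falls also included Calb1 (0.137 ± 0.174 against 8.23 ± 1.37 CPM), Grb10 (5.14 ± 0.912 against 133 ± 1.81 CPM) and the glucose-6-phosphatase gene G6pc3 (0.306 ± 0.0304 against 5.77 ± 1.09 CPM). In all, edgeR called 8595 genes (53.9%), of which 4271 rose and 4324 fell (3739 and 4601 with DESeq2, 3768 and 4644 with DESeq2-type size factors, 3744 and 4665 with upper-quartile factors), and 293 rose and 1341 fell by at least 2-fold. When only these 2 groups were fitted, 7452 genes were called. Lbx1 stood at 79.6 ± 24.5 against 56.0 ± 7.84 CPM (log2 fold change 0.51, SE 0.20, adjusted p = 0.0383). Its call was lost with DESeq2, with other size factors, among genes with a mean of at least 5 CPM, when only these 2 groups were fitted, and without untransduced replicate 2 (0.51), Lbx1WT replicate 1 (0.40) or 2 (0.49) or Lbx1FS replicate 1 (0.52) or 3 (0.25).

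The overlap of both comparisons with the Phox2b group asks which genes changed in both Lbx1 groups. These groups also share the labelled knockout and lower Phox2b, at 23.4 and 13.4 CPM against 109 in the Phox2b group. Changes found in both can therefore not be assigned to Lbx1 itself. Ric3, Ddit4l, Pax8, Gad1, Pax2 and Npy rose with both forms, and Phox2b, Lhx3, Prph, Evx1, Cyp26b1 and Tbx2 fell with both. Slc17a6 fell with Lbx1WT and rose with Lbx1FS. Among the 15943 genes, 789 rose and 956 fell with both forms, where independent lists of the same sizes would share 410 and 378. Another 424 genes changed in opposite directions, where independent lists would share 788. Unchanged groups simulated against the same Phox2b libraries gave 0 in each case (20 simulations). Almost no gene is called in unchanged groups, so this 0 cannot show how much the shared Phox2b libraries add to the overlap. The fold changes correlated across genes with r = 0.488, against 0.476 on average and 0.521 at most in the simulations, and their covariance was 0.180 against a simulated 0.0245. With separate controls, 1 Phox2b library for one form and the other 2 for the other in each of the 6 ways, 521 to 1072 genes changed in the same direction with both forms, 2.43 to 2.84 times the number for independent lists, and r was 0.348 to 0.404. The 1745 genes changed with both forms in the same direction became 1053 without Lbx1WT replicate 1, 1105 without Lbx1WT replicate 2 and 1054 without Phox2b replicate 3.

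Of the 147 genes that rose at least 2-fold with Lbx1WT, 84 also rose with Lbx1FS and 17 fell. Of the 194 that fell at least 2-fold with Lbx1WT, 174 also fell with Lbx1FS and 6 rose. Both comparisons use the same Phox2b libraries, which by itself favours agreement for genes chosen this way. Tested directly between the Lbx1 groups, 33 of the 147 and 99 of the 194 were not called. With Lbx1FS, 50 of the 147 were higher and 64 lower than with Lbx1WT, and 26 of the 194 were higher and 69 lower.

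**Figure D5:**
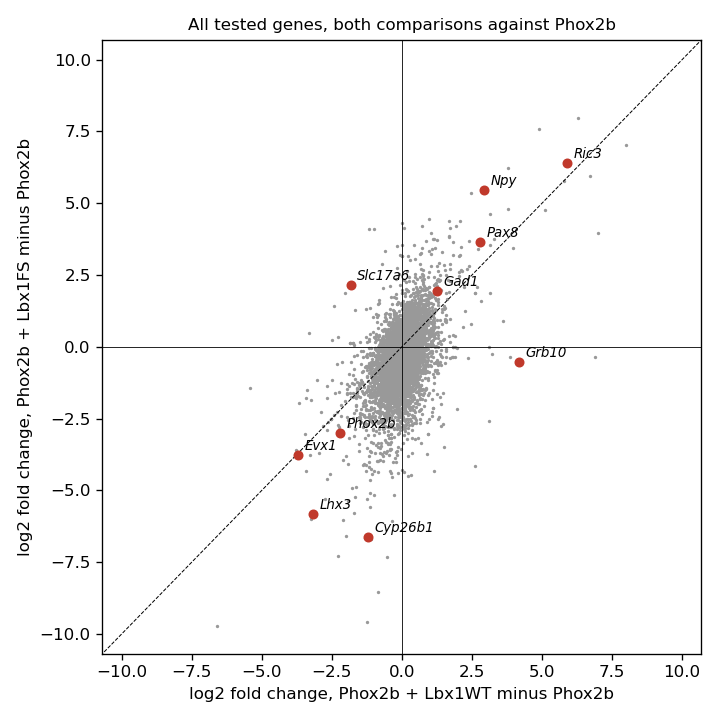
Log2 fold change against the Phox2b group for the 15943 tested genes, with the Lbx1WT group on the horizontal axis and the Lbx1FS group on the vertical axis. Each grey point is a gene, named genes are red and the dashed line marks equal change; Slc17a6 lies at -1.83 and 2.14, Pax8 at 2.79 and 3.63, and Cyp26b1 at -1.21 and -6.62.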

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

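The alternatives without repeated and accession-type gene names and with separate Phox2b controls for both Lbx1 forms were chosen after seeing the data, and all others were planned. No call reversed its direction under the alternatives run. Counts of calls stayed within 1.5 times their value in 141 values with a library left out and in 123 others, and moved further in 15 and 26. The exceptions in the comparison of Lbx1WT with Phox2b were the fit of only the 2 groups compared (4588 genes, 2150 rises, 2438 falls; the cause was not tested) and the stricter threshold of 0.01 (1340 genes, 702 rises, 638 falls), which also left 895 genes changed in the same direction with both Lbx1 forms. A change of at least 2-fold left 3709 genes with Phox2b against untransduced cells (2492 up, 1217 down), 341 with Lbx1WT (147 up, 194 down), 2079 with Lbx1FS against Phox2b (480 up, 1599 down), 1634 with Lbx1FS against Lbx1WT (293 up, 1341 down) and 235 with both forms in the same direction; stricter thresholds give fewer calls by construction. With a library left out, the Lbx1WT count ranged from 1540 (without Lbx1WT replicate 1) to 4292 (without Lbx1FS replicate 2), with 863 to 2218 rises and 677 to 2074 falls. It was 1655 without Lbx1WT replicate 2 and 1579 without Phox2b replicate 3. The count changed in the same direction with both forms ranged from 1053 (without Lbx1WT replicate 1) to 2488 (without Lbx1FS replicate 3), and was 1105 without Lbx1WT replicate 2 and 1054 without Phox2b replicate 3. With separate controls it was 541, 521 and 824 with Phox2b replicate 1, 2 or 3 alone for Lbx1WT and 1072, 1050 and 999 with each alone for Lbx1FS. The cause was not tested. Fewer libraries can lower a count, but the Lbx1WT count rose to 4292 and 3786 without Lbx1FS replicate 2 and 3. Over the fits that left out a library, the other counts ranged from 9988 to 11314 for Phox2b against untransduced cells, 8466 to 9459 for Lbx1FS against Phox2b and 7582 to 8922 for Lbx1FS against Lbx1WT. A group left with 2 libraries was assumed to vary like the others.

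The replicate numbers showed no clear pairing of the libraries. Residual correlations were -0.0429 to 0.135 for same-number pairs and -0.165 to 0.127 for other pairs. Of 12 libraries, 6 were closest to one with their own number, so pairing is not excluded. With the replicate block, the counts were 10725, 2870, 9387 and 8632 in the 4 comparisons. DESeq2 gave 10311, 2910, 9177 and 8340, and leaving out repeated and accession-type names gave 10324, 2711, 9002 and 8297. For the list tests, 1074 values with a library left out and 482 others kept their direction and call, 13 and 42 were no longer called, and 9 and 9 became called. Calls ended by the estimated correlation are given with the results. On ranks, calls ended with Phox2b for noradrenergic (adjusted p = 0.627), dorsal excitatory (0.151), dorsal progenitor and neural progenitor (0.0557 each) and glial genes (0.0975). They ended with Lbx1WT for noradrenergic (0.0808), dorsal excitatory (0.226), dorsal progenitor (0.649) and muscle genes (0.0706), and with Lbx1FS against Phox2b for noradrenergic (0.143), dorsal excitatory (0.135) and dorsal progenitor genes (0.527). Without a filter, calls ended with Phox2b for noradrenergic (0.314) and dorsal excitatory genes (0.0757), with Lbx1WT for muscle genes (0.143), and with Lbx1FS against Phox2b for noradrenergic (0.182) and dorsal progenitor genes (0.186). Among genes with a mean of at least 5 CPM they ended with Phox2b for cholinergic (0.0865), dorsal progenitor (0.152) and retinoic acid genes (0.0507), with Lbx1WT for visceral (0.0729) and muscle genes (0.0777), and with Lbx1FS against Lbx1WT for mesenchyme genes (0.110). Calls arose with Phox2b for Hox genes of paralogue groups 1 to 5 on ranks (0.0308), with DESeq2-type size factors (0.0475) and without a filter (0.0121), and for visceral genes without a filter (0.0249). They also arose with Lbx1WT for p53 targets on ranks (0.0471) and without a filter (0.0328), with Lbx1FS against Phox2b for neural crest genes (0.0493 and 0.0251), and with Lbx1FS against Lbx1WT for interferon genes without a filter (0.0466). The causes were not tested. The scaling alternatives moved the median of all genes by at most 0.0588 (log2). The chi-square per gene between replicates was 10.2 to 29.7 in the Lbx1FS group and 2.26 to 9.91 in the other groups. Spread in the Lbx1FS group thus differed from the like spread that the fit to all groups assumes. Fitting only the 2 groups compared gave 4588 calls for Lbx1WT against Phox2b, 8443 for Lbx1FS against Phox2b and 7452 for Lbx1FS against Lbx1WT. Counts of calls in different comparisons are therefore not measures of effect size. The filter on low counts left 18739 gene names untested.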

Other observations

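The tests of depth, of mesenchyme and endoderm markers, of Lbx1FS replicate 3 and of the Phox2b level were chosen after the result was seen, as were the additional gene lists used here. The first 3 lists are given without the members seen before they were made. Of 12 Wnt target and feedback genes, 10 rose with Phox2b against untransduced cells and 1 fell (median log2 fold change 1.65; camera adjusted p = 1.82e-04, and adjusted p = 0.0174 with an estimated correlation). Between Lbx1FS and Lbx1WT, 11 fell and 1 rose (median -0.85; adjusted p = 0.00100, and adjusted p = 0.0248 with an estimated correlation). With Lbx1FS against Phox2b, 9 fell and 1 rose (adjusted p = 0.0434, and adjusted p = 0.107 with an estimated correlation), and with Lbx1WT the list was not called (adjusted p = 0.108), although the whole list of 15 was called upward there (adjusted p = 0.0486, and adjusted p = 0.0857 with an estimated correlation). Among the members seen before, Lef1, a transcription factor gene of the pathway, stood at 0.372 ± 0.187 CPM in untransduced cells, 17.0 ± 0.182 with Phox2b, 18.8 ± 0.844 with Lbx1WT and 4.49 ± 0.698 with Lbx1FS (n = 3 each). The ubiquitin ligase gene Rnf43, also seen before, followed the same order of levels, at 0.628 ± 0.392, 18.4 ± 1.09, 21.9 ± 1.26 and 4.13 ± 0.347 CPM. Dkk1, which encodes a Wnt antagonist, was lower with Phox2b than in untransduced cells and higher with Lbx1FS than with Lbx1WT, at 3.54 ± 0.531, 0.866 ± 0.128, 0.432 ± 0.113 and 0.758 ± 0.186 CPM.

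Of 19 synaptic vesicle genes, 14 fell and 1 rose with Phox2b (median -0.77; camera adjusted p = 4.31e-05, and adjusted p = 0.0292 with an estimated correlation). The vesicle protein gene Syp stood at 296 ± 8.49 CPM in untransduced cells, 158 ± 3.03 with Phox2b, 141 ± 1.95 with Lbx1WT and 169 ± 5.09 with Lbx1FS. With Lbx1WT against Phox2b, 10 fell and 1 rose (adjusted p = 3.56e-05, and adjusted p = 0.0488 with an estimated correlation), and in both comparisons of Lbx1FS the list was not called. Of 18 genes of the protocadherin gamma cluster, which share exons, 12 fell and 1 rose with Phox2b (adjusted p = 0.0147, and adjusted p = 0.148 with an estimated correlation). With Lbx1FS the counts went the other way without a call for the list, with 8 rises and 4 falls against Phox2b (adjusted p = 0.456) and 7 rises and 4 falls against Lbx1WT (adjusted p = 0.315). The 2 members seen before decided the latter, since the whole list of 20 was called upward there (adjusted p = 0.0123, and adjusted p = 0.173 with an estimated correlation).

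Usp9y had 0 counts in all 9 transduced libraries and several imprinted genes differed strongly from untransduced cells, which may reflect differences between lines. Of 40 imprinted genes not seen before, 21 were called with at least a 2-fold change between Phox2b and untransduced cells, against a median of 8 in random lists (permutation test, one-sided p = 1e-04, the smallest that 10000 lists can give), or 18 of 37 without Mirg, Dlk1 and Dio3. The random lists treat genes as independent, so this p is too small if imprinted genes change together. Between Lbx1FS and Lbx1WT, 18 of the 40 fell and 9 rose (camera adjusted p = 0.0153, and adjusted p = 0.0412 with an estimated correlation). In the other comparisons camera did not call this list (adjusted p from 0.141 to 0.493). Igf2 stood at 16.02 ± 0.930 CPM in untransduced cells, 811 ± 10.8 with Phox2b, 1050 ± 25.6 with Lbx1WT and 411 ± 18.2 with Lbx1FS. In the same order of groups, Meg3 stood at 916 ± 11.5, 0.522 ± 0.282, 0.670 ± 0.151 and 0.448 ± 0.0336 CPM. Peg13 was likewise low in all transduced groups, at 219 ± 6.29, 0.487 ± 0.118, 0.491 ± 0.0672 and 0.199 ± 0.0646 CPM. Grb10 instead differed most with Lbx1WT, at 2.64 ± 0.244, 7.42 ± 0.307, 133 ± 1.81 and 5.14 ± 0.912 CPM. For Usp9y, loss of Y-linked expression as a whole was argued against by the other Y-linked genes (0 of 3 below 0.1 times their untransduced level), and depth by 657 foreseen counts against 0 observed, a test recomputed on Usp9y alone after a version over all Y-linked genes and rescaled to TMM totals. Clone and transduction cannot be separated from group, so both stay open.

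Retinoic acid genes were lower with Lbx1FS than with Lbx1WT, which may reflect a lower retinoic acid response as a whole. Outside the fixed list, 5 of 6 further retinoic acid targets fell and 0 rose, with Tgm2 at 1.25 ± 0.276 against 8.89 ± 1.09 CPM (camera adjusted p = 0.00756, and adjusted p = 0.0545 with an estimated correlation). RNA quality of Lbx1FS replicate 3 alone is argued against, since the median log2 fold change of all 17 list members was -1.07 with that library and -1.08 without it, while a quality difference shared by all 3 Lbx1FS libraries stays open, as their Malat1 levels and mitochondrial shares were all low. A smaller share of mesenchyme-like or endoderm-like cells stays open, as the whole cause or as a part. Of 23 of their markers, 12 fell less than that median of -1.07 or rose, by more than 2 SE. This count cannot decide, since the medians of the mesenchyme and endoderm lists, -0.93 and -1.12, lay on either side of -1.07. Nor need all markers of a cell type fall alike.

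Changes against Phox2b alone were larger with Lbx1FS than with Lbx1WT. A response in proportion to the lower log2 Phox2b level foresees changes with Lbx1WT of 0.735 times those with Lbx1FS. Over 3708 genes chosen on Phox2b against untransduced cells, the ratio of median absolute changes was lower, at 0.350 (95% interval 0.336 to 0.370). The interval was resampled over genes, which are not independent. This ratio cannot decide, since these genes were not shown to respond to Phox2b. Absolute changes also include spread between libraries, which was larger in the Lbx1FS group. The ratio also depended on the choice of genes. It was 0.777 (0.700 to 0.856) for 340 genes changed at least 2-fold with Lbx1WT and 0.266 for 2078 changed with Lbx1FS. A response to the Phox2b level therefore stays open, as the whole cause or as a part, as does a threshold response. The knockout label was not tested. Clone identity differs with the group and stays open, as does the form of Lbx1.

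With 10 splits of the 6 libraries of a comparison, no share under 0.05 can be reached; the real split was the only one, 1 of 10, with as many calls in each comparison. The real counts by edgeR were 10691, 2694, 9330 and 8595, and the highest of the other splits was 0 in each. Other splits mix libraries of both groups, so the difference between groups enters their spread and few calls follow by design. At an unadjusted p under 0.05 the other splits reached 190, 462, 991 and 1904 genes, and DESeq2 called at most 0, 0, 1 and 369.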
